A study of Schizosaccharomyces pombe with 28 samples.

How the data were processed

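The series holds 28 two-colour Agilent 60-mer arrays of DNA from chromatin immunoprecipitation (ChIP) in the fission yeast Schizosaccharomyces pombe. Per the labels' protocols, ChIP DNA carried Cy5 and whole-cell extract DNA carried Cy3 on each array, so a positive log ratio means enrichment in the ChIP. The antibodies were against histone H3 trimethylated at lysine 9 (H3K9me3), H3 dimethylated at that lysine (H3K9me2), or a myc tag on Raf2. Cultures for the myc ChIP were held in the cold before fixation and crosslinked further, per the labels' protocols, which sets those 4 arrays apart from the other 24. The label words KD, REIID, EMS32 and clr4CD are not explained in the sources used here and are kept as written.

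The spot intensity values were made by the authors with Agilent Feature Extraction 12.0.3.1, per the file headers. The processed intensity of each channel had its background subtracted, was spatially detrended and was dye-normalized by a linear method without lowess, per the file headers. Multiplicative detrending had been applied in most channels and not in all. The deposited series table holds linear ratio values of Cy5 over Cy3, as settled by setting each column against the scanner file of its sample. Of its 28 columns, 23 equalled that ratio within 0.01 on the log2 scale. The column of H3K9me2 REIID G13D replicate 1 correlated at 0.853 with its own array and at 0.996 with H3K9me3 REIID G13D replicate 1. The 4 later H3K9me2 columns correlated at 0.09 to 0.119 with their own arrays, and those 5 columns entered no test. Column medians lay between 0.886 and 1.207 and not all at 1, so the table was not median centred.

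From the scanner files, log2 of the processed Cy5 over the processed Cy3 intensity was computed for 41551 probes, leaving out 1417 control spots. Spots flagged as outliers and spots whose Cy3 was not well above background were set to missing. A difference of array means can rest on different probes where some are missing, so differences over the probes measured on both arrays were also computed. Each array was centred on its median, with no loess or quantile step. Probe names give a contig and a position that is a multiple of 300 bp, and the genome build is not given in the sources used here. Positions on the array were offset from the reference at hand, so no coordinate was converted and no probe was tied to a gene. The gene lists chosen beforehand (meiotic islands, marker genes, euchromatic controls, Tf2 elements, histone, heterochromatin factor and thiamine genes, and telomere-linked helicases) were therefore not placed. 18 regions fixed before the data were examined were used instead: the mat contig of the array, which carries the silent mating-type interval, its neighbourhood and flanks on chromosome 2, the outer repeats, core and flanks of each centromere, 4 subtelomeres and both ends of chromosome 3. For the centromeres and for the mat neighbourhood and flanks, approximate kb positions of a reference build served as boundaries, unconverted. The middle of each centromere was taken as its core. Core, outer repeat and flank labels are therefore approximate, also for the outer repeats used for scaling below. Windows of 2000 bp with at least 3 measured probes took the place of genes. Windows are named by a rule fixed beforehand: the 10 largest rises and falls, among windows with a called probe and replicates that do not overlap in replicated comparisons, or among windows at a log2 ratio of at least 1 in either array otherwise, and any window of the mat contig.

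Probe tests used limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with data.table (version 1.17.8), two-sided, with Benjamini-Hochberg adjustment at 0.05. The 8 REIID arrays with 2 per group were fitted together (4 residual degrees of freedom). The nmt1 arrays were fitted with genotype, the rank of the uM label and their product. Region shifts were tested with fry, which asks whether the probes of a region move on balance in 1 direction, adjusted over the 18 regions. Comparisons of 1 array with 1 array carry no test. Each region's difference was placed among 10000 random runs of neighbouring probes outside the regions, matched on Cy3 tertile and not on ChIP signal, as a description of those arrays. Nothing states that replicates came from separate cultures, so p-values measure only the spread between these arrays. The number of arrays limits the precision: an exact permutation test of 2 against 2 cannot go below 0.333.

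Slides were read from the files. The 28 arrays lay on 8 slides, each scanned on a single date. Replicate 1 of the WT and G13D arrays of both marks shared a slide, and replicate 2 shared a slide within each mark, so the replicate number and the slide give the same block. Deviations of same-numbered H3K9me3 arrays from their group means correlated at 0.851 over probes, and those of H3K9me2 arrays at 0.002. The nmt1 WT and nmt1 G13D arrays lay on separate slides, so slide and genotype cannot be told apart there.

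The tests were tested on simulated data made from the real group means, with a set of probes changed by a log2 of 1, 2 or 4 and the mat contig shifted. 2 noise models were run. The model tried first drew noise from each probe's moderated variance. It gave 6 false calls for the group-mean fit, 61 for the replicate-block fit (17.2% of its calls) and 21 for the nmt1 fit (7.5%), above the 5% aimed at in the last 2. The second, taken up after those counts were seen, drew variances from the prior that limma fits, which is the test's own assumption, and gave 9, 11 and 12. The 9 were 6.2% of the calls of the group-mean fit, above the 5% aimed at. Under the second model, on 40186 probes, the group-mean fit recovered 0% of changes of log2 1, 41.4% of log2 2 and 95.6% of log2 4. The replicate-block fit recovered 16.4%, 98.1% and 100%, and the nmt1 fit on 40911 probes 13.5%, 86.2% and 100%. Under the first model the shares at log2 1 were 2.9%, 88.8% and 42.2% for the group-mean, replicate-block and nmt1 fits. The changed probes lay outside the regions, and noise was drawn independently for each probe and array. Real same-numbered H3K9me3 arrays shared deviations, so these shares do not carry over to the regions. Given the false calls of the first model, calls of the replicate-block fit may hold more false calls than its threshold states.

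Signal over background sets the precision here. Median Cy5 was 23.56 to 77.72 times its background, except on the nmt1 WT array at 0 uM, where it was 4.33 times, with 7836 probes not well above background in Cy5. No spot was saturated. The alternatives planned beforehand were normexp background correction with an offset of 50 (on median signals, since the files hold no mean signals), loess, the deposited table, other centring and filters, each replicate or uM label left out, a replicate block, a 2-fold minimum, 1000 bp windows, other region summaries, and camera. Cy5 alone, the nmt1 fit without its dim array, and the nmt1 fit relative to the outer repeats were added after seeing the data. The REIID test with Cy5 alone was at first taken over paired probes (which gave a larger difference), and was changed to the difference of region means used elsewhere. The random seeds were fixed, and figures were drawn with matplotlib 3.10.9.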

Results

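H3K9 methylation and Raf2 binding were profiled on 28 arrays. H3K9 methylation marks heterochromatin and is deposited by the methyltransferase Clr4. Raf2 is a subunit of the complex that holds Clr4, and hht2 encodes histone H3. H3K9me3 and H3K9me2 were measured in WT and hht2 G13D strains labelled REIID (2 arrays per group), in REIID clr4CD and G13D clr4CD strains (1 array each), and in WT and EMS32 strains labelled KD (1 array each). Raf2-myc was measured in the 4 REIID genotypes (1 array each). H3K9me3 was also measured in strains with hht2 or hht2 G13D under the name nmt1, a promoter repressed by thiamine, at titles of 0, 01, 05 and 20 uM (1 array each). All values are centred log2 ratios of ChIP over whole-cell extract, and coordinates are those of the array, whose genome build is not given in the sources used here.

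The comparison of REIID G13D with WT asked how the histone genotype relates to each mark. H3K9me3 over the mat contig had a mean of 4.60 ± 1.48 (SD, n = 2) in WT and 3.14 ± 1.68 (SD, n = 2) in G13D. The difference was -1.32 on the slide of replicate 1 and -1.60 on that of replicate 2. The mat neighbourhood on chromosome 2 differed by -1.07 and -1.34, and the mat flanks by -0.95 and -1.19. Both may share sequence with the mat contig and are no independent support for it. The outer repeats of centromere 1 differed by less, -0.28 and -0.49. The left end of chromosome 3 was higher in G13D, by 1.07 and 0.55. In all, 16 regions were lower and 2 higher on both slides, but relative to the outer centromeric repeats of the same array 6 were lower and 10 higher on both, and the mat contig differed by -0.94 and -1.07. None of the 18 regions passed fry (lowest adjusted p = 0.893, or 0.53 with the slide as a block). Relative to the outer repeats none passed either, with an adjusted p in fry of 0.0734 at the left end of chromosome 3 and 0.143 over the mat contig. The replicates lay far apart, with 7.47 and 4.82 in WT at the outer repeats of centromere 1.

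**Figure D1:**
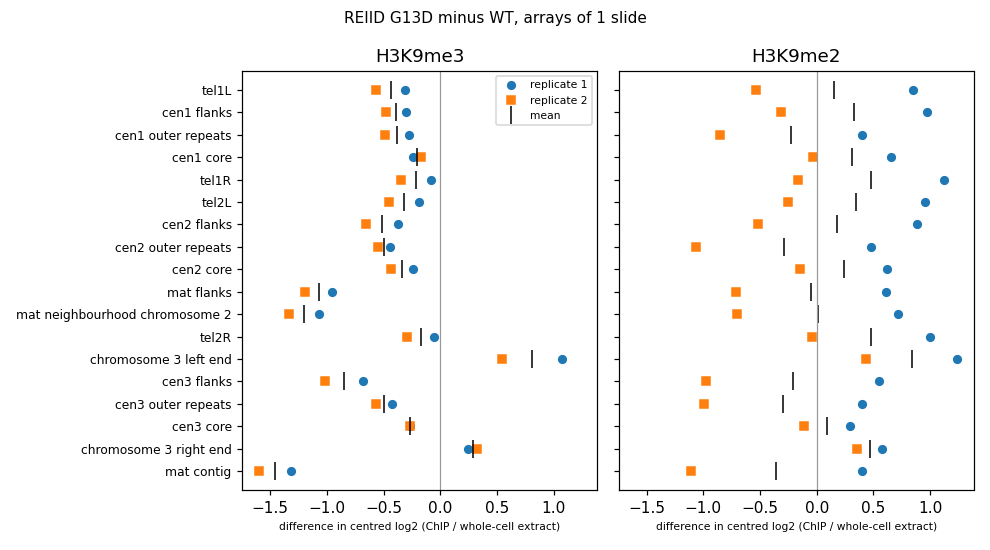
Difference of REIID G13D minus WT in centred log2 ratio (horizontal axis) for the 18 regions (vertical axis), with a point for each slide and a bar for the mean. H3K9me3 over the mat contig lies at -1.32 and -1.60, whereas the H3K9me2 points lie on opposite sides of 0 in 16 regions.

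Along the mat contig, H3K9me3 was lowest in G13D relative to WT between 22000 and 27999. The window from 24000 to 25999 differed by -3.45 and -4.30, and that from 22000 to 23999 by -3.46 and -3.13 (-3.46 and -3.77 over the probes measured on both arrays). The windows from 30000 to 31999 and from 32000 to 33999 differed by -0.18 and -0.57, and by -0.19 and -0.60. At the level of single probes, limma called 0 probes at an adjusted p of 0.05 in the fit of group means, with 262 probes at an unadjusted p under 0.05. With the slide (the replicate number) as a block, 0 probes were higher and 35 lower, of which 21 lay on the mat contig, 4 in its flanks and 2 in its neighbourhood. A run of 5 called probes on chromosome 3 from 115500 to 116700, chosen after its values were seen, had values of 7.73 and 5.71 in WT and 3.87 and 1.62 in G13D. The called run on the mat contig from 22800 to 27000 had similar ones, 7.92 and 5.69 in WT and 4.62 and 1.78 in G13D. Whether the chromosome 3 run reads a separate place in the genome was not tested.

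**Figure D2:**
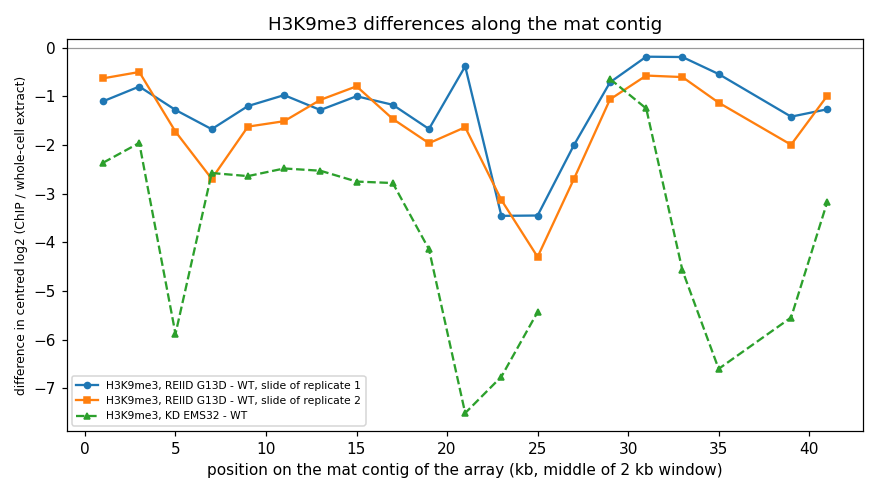
Difference in centred log2 ratio of H3K9me3 (vertical axis) in 2 kb windows along the mat contig (horizontal axis, kb), for REIID G13D minus WT on each slide and for KD EMS32 minus WT. REIID differences reach -3.45 and -4.30 in the window from 24000 to 25999 and lie at -0.18 and -0.57 from 30000 to 31999. The KD line has a gap where the KD arrays had almost no whole-cell extract signal.

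Over the mat contig, H3K9me2 in WT had 4.27 ± 0.47 (SD, n = 2) and G13D 3.92 ± 0.59 (SD, n = 2), with a difference of 0.40 on one slide and -1.11 on the other. In H3K9me2 the window from 22000 to 23999 differed by -1.16 and -2.58, that from 24000 to 25999 by -1.06 and -2.94 and that from 26000 to 27999 by 0.18 and -1.48. The slides differed in sign in 16 of the 18 regions. Relative to the outer centromeric repeats of the same array, 12 regions were higher and 2 lower in G13D on both slides, with 0.71 and 0.79 at tel1R (the right subtelomere of chromosome 1) and -0.02 and -0.15 over the mat contig, and fry called 0 regions in that scaling too. The ends of chromosome 3 were higher in G13D on both slides, the left by 1.24 and 0.44 and the right by 0.58 and 0.35. No region passed fry (lowest adjusted p = 0.988, or 0.858 with the slide as a block). In the fit of group means limma called 0 probes (141 at an unadjusted p under 0.05), and with the block 6 were higher, all on subtelomeric plasmid contigs, and 43 lower, of which 3 lay on such contigs, 2 on the mat contig and 38 outside the regions. The difference between the marks was tested as an interaction: limma called 0 probes (133 at an unadjusted p under 0.05), and 0 with the block (1824). The mat contig differed by -1.71 and -0.50 more for H3K9me3 than for H3K9me2 (fry, adjusted p = 0.927), and by -0.93 and -0.92 relative to the outer repeats, a scaling in which the difference between the marks was not tested by region.

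In the KD strains H3K9me3 over the mat contig was 4.44 in WT and 0.70 in EMS32, a difference of -3.79 over probes measured on both arrays. This was below each of 10000 random runs, which reached -2.25. The runs were not matched on ChIP signal, and probes outside the regions had a mean of 0.01 in WT. Most runs thus had little signal to lose, and this place says little. The mat neighbourhood went from 4.89 to -0.12, the left end of chromosome 3 from 2.74 to 0.70, and tel1R from 5.87 to 3.61. The outer repeats of centromere 1 stood at 6.74 and 6.29. H3K9me2 gave 3.33 and 0.85 over the mat contig, with the outer repeats of centromere 1 higher in EMS32 by 0.58. The window of the mat contig from 20000 to 21999 differed by -7.51 in H3K9me3, and that from 28000 to 29999 by -0.64. These pairs have 1 array per group and no replicate check. The genotype label of the EMS32 array reads EMS32 for H3K9me3 and G13D for H3K9me2.

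Whole-cell extract DNA differed between the KD and the REIID arrays at stretches chosen after their values were seen, so it is no independent check on the labels. Cy3 at a stretch of 3 mat contig probes, chosen after its values were seen, lay between -10.55 and -8.10 (log2, centred) on the 16 REIID arrays outside the nmt1 set and between -0.99 and 1.38 on the 4 KD arrays. At a stretch of 12 mat contig probes, chosen in that way too, the reverse held, with -9.56 to -8.31 on the KD arrays and -2.07 to 0.08 on those 16. The 8 nmt1 arrays had -9.62 to -4.56 at the stretch of 3 probes and -1.47 to -0.20 at that of 12. Spots without clear Cy3 signal were set to missing, so mat contig means of the KD and the REIID arrays rest on different probes.

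In the clr4CD strain, methylation of the subtelomeres was higher than in WT replicate 2 on the same slide. H3K9me3 at tel1R was 5.43 in clr4CD and 2.06 in WT replicate 2, and 4.62 in G13D clr4CD against 1.71 in G13D replicate 2. H3K9me2 at tel1R was 6.84 against 3.20 and 5.95 against 3.04. Of the 10 windows with the largest rise 9 lay in tel1R for H3K9me3 and 8 for H3K9me2. The window from 5544000 to 5545999 on chromosome 1 was higher by 4.77 in H3K9me3 and by 5.31 in H3K9me2. These comparisons have 1 clr4CD array each and no replicate check. Against WT replicate 1, on another slide, H3K9me3 at tel1R was higher by 1.21, while the other subtelomeres (tel1L on the left of chromosome 1, tel2L and tel2R on chromosome 2) differed by -0.62, -0.15 and -0.41. The outer repeats of centromere 1 also differed by -2.10 between those slides, and relative to the outer repeats of each array the 4 subtelomeres were higher in clr4CD, tel1R by 3.42 and the others by 1.59, 2.07 and 1.80. Scaled in that way against WT replicate 2 on the same slide, the others rose by less, 1.275, 1.435 and 1.015. A part of the values across slides may thus belong to the slide. In H3K9me3, G13D clr4CD differed from G13D replicate 1 by 0.47 at tel1R, and by 3.01 relative to the outer repeats. At tel1L, tel2L and tel2R it differed by -0.83, -0.17 and -0.44, and by 1.71, 2.37 and 2.09 relative to the outer repeats. H3K9me2 was higher than in replicate 1 at the 4 subtelomeres without that scaling. In clr4CD it exceeded WT replicate 1 by 4.10 at tel1R and by 2.16, 2.37 and 1.97 at tel1L, tel2L and tel2R. In G13D clr4CD it exceeded G13D replicate 1 by 1.98 at tel1R and by 0.89, 0.87 and 0.63 at the others. Over the mat contig, H3K9me3 was 3.25 in G13D clr4CD, 1.95 in G13D replicate 2 and 3.79 in clr4CD. The window from 24000 to 25999 of the mat contig was higher by 3.87 in G13D clr4CD than in G13D replicate 2. It stood at 5.329 in G13D clr4CD and at 4.485 in G13D replicate 1, on another slide. Against that replicate the mat contig as a whole differed by -1.09, or by 1.45 relative to the outer repeats (1.01 against replicate 2). H3K9me2 over the mat contig was 4.54 in G13D clr4CD, 3.50 in G13D replicate 2 and 4.34 in G13D replicate 1.

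Raf2-myc at tel1R was 2.77 in WT and 0.61 in G13D on the same slide, and 2.35 and 1.07 at tel1L. The tel1R difference of -2.16 lay below each of the random runs, which says little, since those runs were not matched on ChIP signal. Over the mat contig Raf2-myc was 1.83 and 1.38, and in the window from 24000 to 25999 it differed by -2.41. The outer repeats of centromere 1 stood at 3.13 in WT and 3.35 in G13D. In G13D clr4CD and clr4CD, which shared another slide, tel1R stood at 3.23 and 3.59 and the mat contig at 2.29 and 2.20. Each Raf2-myc genotype has 1 array and no replicate check.

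In the nmt1 arrays, mean H3K9me3 was lower in G13D than in WT in 18 of 18 regions, with tel1R the only one to pass fry and the outer repeats of centromere 1 differing by -0.61. Relative to the outer repeats 4 regions were lower at all 4 labels (tel1R, tel1L and both ends of chromosome 3), 7 were higher at all 4, and the mat contig differed by 0.01. At tel1R WT had 4.18 ± 0.47 (SD, n = 4) and G13D 1.87 ± 0.88 (SD, n = 4), lower at each of the 4 uM labels, and fry called the shift (adjusted p = 0.00706). The call was lost with an estimated correlation (camera, adjusted p = 0.0845). The exact permutation test over the 35 splits gave p = 0.0286, the smallest it can give, with an adjusted p = 0.0857 over 18 regions. With the uM labels kept matched only 8 splits remain, and the smallest exact p is 0.125. tel1L had 4.28 ± 0.34 (SD, n = 4) and 3.19 ± 1.05 (SD, n = 4), and the mat contig 2.93 ± 0.21 (SD, n = 4) and 2.33 ± 0.80 (SD, n = 4). Without the 0 uM label tel1L passed fry (adjusted p = 3.3e-04) at a difference of -0.72, and the mat contig difference was -0.30. limma called 5 probes higher and 179 lower in G13D, of which 78 lay in tel1R, 31 in tel1L, 21 in tel2L and 19 in tel2R. Relative to the outer repeats tel2L and tel2R were higher in G13D at all 4 labels, by 0.12 and 0.22 on average. The window with the largest fall, on chromosome 1 from 5546000 to 5547999, was at 4.62 ± 0.60 (SD) in WT and 0.78 ± 1.01 (SD) in G13D. The only window named as higher, on chromosome 3 from 790000 to 791999, differed by 0.49.

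The G13D array at 0 uM had the lowest value of the 8 at tel1R, at 0.58, and over the mat contig, at 1.15, where G13D at 20 uM had 2.93. That array stood apart as a whole, with its outer repeats at 3.87 against 4.83 to 5.40 on the other nmt1 arrays and 9572 enriched probes outside the regions. Relative to the outer repeats the tel1R difference between genotypes was -1.82 at 0 uM and -1.84 at 01 uM. The slope over the labels in G13D passed fry in 6 regions, tel1R, the mat contig, its neighbourhood and the flanks of the 3 centromeres (adjusted p = 0.0482 each), and no region passed in WT. The difference of slopes passed in none of these (fry, adjusted p = 0.52 at tel1R). limma called 0 probes for the slope in either genotype (6437 in WT and 6014 in G13D at an unadjusted p under 0.05). limma called 0 probes for the difference of slopes between the genotypes (2454 at an unadjusted p under 0.05). The call at tel1R was lost without the 01, 05 or 20 uM label (fry, adjusted p = 0.12, 0.155 and 0.127) and with normexp background correction (fry, adjusted p = 0.0538). The tel1R difference itself lay between -2.88 and -1.69 over the 20 alternatives. The WT and G13D arrays lay on separate slides, so the genotype cannot be told apart from the slide.

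**Figure D3:**
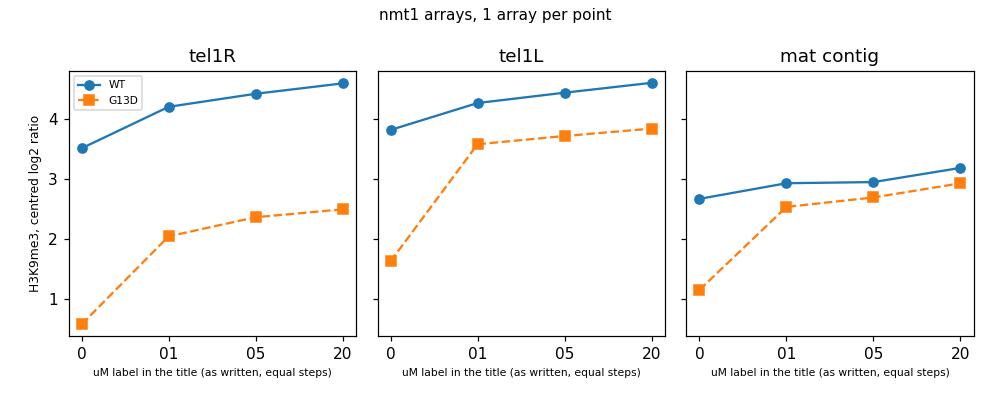
H3K9me3 as centred log2 ratio (vertical axis) against the uM label of the title (horizontal axis, equal steps), with 1 array per point, for tel1R, tel1L and the mat contig. G13D lies below WT at each label in all 3 panels, and its lowest point over the mat contig is 1.15 at 0 uM.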

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

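The tests of Cy5 alone, of immunoprecipitation efficiency, of other sequence copies and of the slide were chosen only after the results they bear on had been seen. The recount over the 35 sample splits was planned beforehand, but what it should show was written down only after those results.

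H3K9me3 at the ends of chromosome 3 moved in opposite directions in the REIID and the nmt1 arrays. At the left end G13D minus WT was 0.81 over the 2 REIID slides, and -1.22 over the 4 nmt1 labels, and at the right end 0.29 and -0.82. Both ends were picked because each slide and each label had the direction of its mean, so that agreement is no support. Mean H3K9me3 in nmt1 G13D was lower in 18 of 18 regions, so a region that rose in REIID would move the other way. The difference itself was not tested. The nmt1 genotypes lay on separate slides. At the left end the 0 uM label gave -2.59, and the mean without it was -0.76. The REIID value at the left end was 0.27 with Cy5 alone and 1.40 with loess. The subtelomeric plasmid contigs of the array, which lie outside the 18 regions, had more H3K9me2 in G13D than in WT by 0.68 on average (0.96 and 0.40 on the slides), although with the slide as a block limma called 3 probes there lower beside 6 higher, while H3K9me3 there differed by -0.06 and -0.45. They were picked because H3K9me2 was higher on both slides. All 129 probes of these contigs, and the 49 and 39 of the left and right end of chromosome 3, carry name suffixes other than R. The alternative with unsuffixed or R probes could not be run there, so signal from other copies of the sequence was not checked.

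The lower H3K9me3 over the mat contig in EMS32 and in REIID G13D was weighed against 2 technical explanations. Cy3 that is dimmer where the ChIP signal is strong could enlarge a log ratio, and no value for such a relation is given here. With Cy5 alone the difference was still -3.02 in EMS32 and -1.11 in REIID G13D, so dimmer Cy3 would not account for the whole of it. Whether it accounts for a part was not tested. If lower immunoprecipitation efficiency of the G13D arrays lowered all regions alike, no difference relative to the outer centromeric repeats would remain. That difference was -1.01 ± 0.09 (SD over 2 slides). The 2 WT arrays did not differ alike, with 7.43 and 4.77 over the outer repeats, 5.65 and 3.56 over the mat contig and 2.73 and 0.84 at tel2R. The scaling therefore does not settle this explanation. A biological difference between the genotypes stays open as a hypothesis, since fry called no shift in the 2 REIID replicates and EMS32, with 1 array per group, had no test.

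Of 11 mat contig probes between 28000 and 31999, the 8 measured on both arrays kept their signal in EMS32, with changes of -0.55 ± 0.23 in H3K9me3 and 0.68 ± 0.22 in H3K9me2 (SD over probes), while the rest of the contig changed by -4.09 and -2.76. A candidate explanation is signal from other copies of the sequence, such as centromeric repeats, which changed by -0.43 and 0.58. The largest gap between the means of these probes and of the repeats was 0.12 over both marks. Methylation kept at this stretch at the level of the repeats would give the same values, and all 11 probes are unsuffixed or have the suffix R, as are 22 of 215 outer repeat probes. The stretch was chosen after its values were seen and leaves out the next window, which changed by -4.58.

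The comparison of nmt1 G13D with WT gave 184 called probes, and 1 of the 35 splits, the real one, gave as many. The highest of the other splits gave 0. The arrays are matched by uM label, and only 8 of the splits keep 1 array of each label on each side, too few for a share under 0.05. At an unadjusted p under 0.05 the real split had 3202 probes and another of the 35 had 3935, while the highest of the other matched splits had 2986. Lower immunoprecipitation efficiency, if it lowered all regions alike, predicts no difference at tel1R relative to the outer repeats, and that was -1.69 ± 0.16 (SD over 4 labels). In that scaling 5 of the 18 region means were lower in G13D and 13 higher, with 0.12 at tel2L, 0.22 at tel2R and 0.01 over the mat contig. For most of the regions lower efficiency therefore stays open. The REIID WT arrays did not differ alike over the regions, so an efficiency that lowers regions unevenly stays open at tel1R too. The real split is also the split by slide: 0 slides hold both genotypes, so genotype and slide cannot be told apart.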

How the results depend on the processing

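Cy5 alone and 2 of the nmt1 alternatives were chosen after seeing the data, and the cause of the changes below was not tested unless stated. With a replicate block, which the slide block repeats, REIID G13D against WT gave 35 called probes for H3K9me3 and 49 for H3K9me2, against 0 in each without it, 0 for the difference between marks, and no called region. H3K9me2 gave 22 with only its 4 arrays. With a preset correlation, camera called 16 regions for H3K9me3 and 11 for H3K9me2, and with an estimated one 0. Leaving out each REIID replicate, where the lone array is assumed to vary like the others, gave 0 called probes and regions throughout. The H3K9me3 difference then ranged from -2.65 to -0.27 over the mat contig, -0.57 to 2.19 at the left end of chromosome 3, -1.81 to 1.05 at the outer repeats of centromere 1 and -1.42 to 0.99 at tel1R, and that of H3K9me2 over the mat contig from -0.776 to 0.063. With Cy5 alone the left end of chromosome 3 was at 0.27 against 0.81 in H3K9me3 and at 0.22 against 0.84 in H3K9me2. Relative to the outer repeats the difference turned to 0.073 at the outer repeats of centromere 1 and 0.24 at tel1R, and with loess to 0.122 and 0.067.

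The nmt1 count of 184 became 62 without the 05 uM label, 83 without the 20 uM label, 118 without the dim WT array at 0 uM, 112 with Cy5 alone and 5984 relative to the outer repeats, where subtracting the repeats shifts every probe of an array. There the mat contig difference turned to 0.01. The 1-array differences that were put through all alternatives, on arrays of a single slide, kept their sign, while many H3K9me3 differences from replicate 1 on another slide, though not those at tel1R, reversed relative to the outer repeats (for example clr4CD against WT, tel1L -0.62 to 1.59, tel2L -0.15 to 2.07 and tel2R -0.41 to 1.80, and G13D clr4CD against G13D, mat contig -1.09 to 1.45). The former moved by more than the SD between the within-slide REIID differences of that region as follows. For EMS32 in H3K9me3 over the mat contig, loess gave -2.76, the deposited table -3.40, no Cy3 filter -3.38, Cy5 alone -3.02, the median -2.75, probes unsuffixed or with the suffix R (called unique probes here) -3.58 and values relative to the outer repeats -3.36. For clr4CD at tel1R in H3K9me3 loess gave 2.58, Cy5 alone 2.63, the median 3.93, unique probes 4.42 and relative values 3.06, and in H3K9me2 Cy5 alone gave 2.58 and unique probes 5.01. For Raf2-myc at tel1R normexp gave -2.70, Cy5 alone -1.70, the median -2.42, unique probes -2.61 and relative values -2.36. Of the other 1-array values, EMS32 in H3K9me3 at the left end of chromosome 3 was -0.60 with loess, -1.12 with Cy5 alone and -1.61 with relative values. G13D clr4CD against G13D replicate 2 in H3K9me3 over the mat contig was 0.73 with Cy5 alone, 0.95 with the median and 1.01 with relative values. Raf2-myc in G13D over the mat contig was -0.13 with the median and -0.82 with unique probes. Removing saturated spots removed none. The slide block could not be fitted in the nmt1 arrays, nor the deposited table used for H3K9me2 REIID.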

Other observations

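A stretch of 27 neighbouring probes in the middle of chromosome 1 carried almost no whole-cell extract signal on the 16 REIID arrays outside the nmt1 set and the 4 KD arrays, with centred log2 Cy3 of -10.47 to -9.14 and -8.89 to -8.17. On the 8 nmt1 arrays it was -0.70 to -0.23. This stretch was chosen after its values were seen.

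In G13D clr4CD against G13D replicate 2, the windows with the largest falls in the log ratio of the H3K9me2 ChIP lay on the mitochondrial contig. The one from 6000 to 7999 stood at -0.13 and 1.30. Whether that signal is methylation or background of the ChIP was not tested. Raf2-myc in clr4CD was higher than in WT beyond the fixed subtelomere, by 2.37 in the chromosome 1 window from 5524000 to 5525999, with the arrays on separate slides. The same window was lower in G13D clr4CD than in clr4CD on 1 slide, at 0.46 and 2.79.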
